A study of Mus musculus with 4 samples.

How the data were processed

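The data are the gene tables of 4 RNA-seq libraries of mouse keratinocytes, 1 per group, and each table gives a gene symbol, an FPKM value and a count. Per the submitters' processing notes, the tools were Trim Galore 0.4.4, HISAT2, featureCounts of the Subread package and edgeR, with genome build mm10. Their order and settings, the gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Total RNA was extracted and the libraries were made by a sequencing company, per the labels' protocols.

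The counts deposited by the authors are whole numbers per gene and are not normalized. Every one of the 13102 deposited genes exceeds 1 CPM in at least 2 of the 4 libraries, and 387 exceed it in exactly 2, so a gene expressed in 1 library alone is not analysed here. The FPKM values deposited by the authors were checked against the counts and used otherwise only for the gene length that they imply. They imply library sizes of 1.02, 1.05 and 1.07 times that of untreated WT in the IL-17A WT, Il17rc KO and Il17rd KO tables, which are the ratios of library totals times TMM factors computed here. There were 17 symbols that a spreadsheet had turned into dates, and they are counted but not named.

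Library sizes were scaled with TMM factors (edgeR 4.0.16) over the 4 libraries. The factors were 0.963, 0.984, 1.01 and 1.04 for untreated WT, IL-17A WT, IL-17A Il17rc KO and IL-17A Il17rd KO. CPM values are counts over these scaled sizes. Log2 ratios use a prior count of 2. The interval of a ratio is the exact 95% conditional binomial (Clopper-Pearson) interval of the counts, which covers counting error only and takes reads as independent. Reads without molecular identifiers are not independent molecules, so the interval is likely too narrow even for that error. With 1 library per group there is no residual variation to test against, so no p-value was computed. In its place stands a rule of size fixed before the data were examined, which calls a gene higher or lower at 2-fold or more with an interval that excludes 1, among the 12934 genes with a mean of at least 1 CPM over the 4 libraries. A call describes 2 libraries, and between-dish variation can produce it. Folds against 0 counts are lower bounds computed from a floor of 3 counts per library. Levels in figures carry exact 95% Poisson intervals.

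The comparisons, fixed at the same time as the rule of size together with the gene lists and the named-gene rule, are IL-17A WT against untreated WT, each knockout against IL-17A WT, and the knockouts against each other, with each knockout against untreated WT as a side value. For each of 30 gene lists the number of members called and the median log2 ratio are given, with the percentile of the median among 10000 random lists of the same size matched in 20 bins of mean expression. The percentile describes these libraries. Named are Il17rc, Il17rd and Il17ra, the 12 genes each way whose interval lies furthest from 1 in the first 3 comparisons and 6 each way in the knockout comparison, up to 4 members of each list with the largest log2 ratio in size, and the 8 genes furthest above untreated WT in all libraries. Gene models without a proper name are counted but not named. The text does not give every gene that the rule selects. Further members of the lists past the size rule, and Lcn2, Xist, Arg1, F2rl1, Sox11, Pdpn, mt-Co1, Gm28661 and the genes with opposite calls in the knockouts, were named after their values were seen.

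The IL-17A WT library enters 3 comparisons. Its counts were split at random 100 times, and unchanged libraries were simulated 100 times, with counting error only and with the spread estimated over the 4 libraries as if they were 1 group (a biological coefficient of variation of 0.328). That spread holds the real differences too. The simulations used its trend over expression and drew genes independently. It is therefore no upper bound for genes that vary more than the trend or that vary together. The size rule was tested on simulated data for the comparison of IL-17A WT with untreated WT, with 200 of 13102 genes changed. With counting error only, 54.0% of genes changed 2-fold, 96.0% changed 4-fold and 98.0% changed 8-fold were called in the right direction, and 0.0787% of unchanged genes were called. With the 1-group spread 50.0%, 94.0% and 98.0% were called, and so were 15.6% of unchanged genes.

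Symbols were matched to GENCODE M21 (GRCm38), which placed 12832 of the 13102 rows, and coordinates come from it. The longest transcript of each gene was aligned to all transcripts so chosen with BLAST+ 2.17.0. A gene has a near-identical copy where another annotated gene matches at 95% identity or more over at least 50% of either sequence, which held for 2473 genes. Reads of such genes can be assigned to either copy, and their values are uncertain. Position and strand of the matches were not checked, so some of the matching genes may overlap the gene itself rather than lie elsewhere. Where genes overlap on opposite strands the reads cannot be told apart if strand was not used.

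Alternatives planned at that time were total counts per library, DESeq2 1.42.0 size factors, no filter on mean CPM, a mean CPM of at least 5, a prior count of 0.5, at least 3-fold, an interval that excludes 1.5-fold and thinning to equal depth. Added after seeing the data was leaving out pseudogenes, mitochondrial genes, unmatched genes and genes with near-identical copies. Also added then was removing the trend of the log2 ratio on GC content and gene length. GC content was that of the longest transcript, and length was that implied by the counts and FPKM values. Calculations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.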

Results

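RNA was sequenced from primary epidermal keratinocytes, the main cells of the outer layer of the skin, taken from neonatal C57BL/6 mice and kept in culture for 48 h. The series holds 4 libraries. One group is untreated wild-type (WT) cells. The other groups received interleukin-17A (IL-17A), an inflammatory cytokine of the skin, at 100 ng/mL for 8 h, and are WT cells, cells of Il17rc knockout (KO) mice and cells of Il17rd KO mice. Il17rc and Il17rd encode members of the IL-17 receptor family. Each group has 1 library, so no difference described here has a replicate check, and no p-value was computed. An untreated library of either knockout was not analysed here, so the effect of a genotype and its effect on the response to IL-17A cannot be separated.

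Total counts over the deposited genes were 19904695 in untreated WT, 19890946 in IL-17A WT, 19799746 in IL-17A Il17rc KO and 19711866 in IL-17A Il17rd KO. Levels are given as CPM, the counts of a gene relative to the scaled size of its library. A gene is called higher or lower in a library when it differed by at least 2-fold from the other library and the exact 95% counting interval of the ratio excluded 1. The rule was applied to 12934 genes. Ratios are followed by that interval in parentheses, which covers counting error only, and it describes these libraries, not the conditions.

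The targeted genes come first, since they check the labels. Il17rd (chromosome 14, 27038941 to 27107286, plus strand, GRCm38) had 252 counts in untreated WT, 265 in IL-17A WT, 150 in IL-17A Il17rc KO and 5 in IL-17A Il17rd KO. It was 55.6-fold lower (23.5 to 173) in the Il17rd KO library than in IL-17A WT. Il17rc (chromosome 6, 113471427 to 113483140, plus strand) had 2729, 1152, 439 and 1718 counts in the same order. It was 2.69-fold lower (2.41 to 3.01) in the Il17rc KO library than in IL-17A WT and 3.82-fold lower (3.44 to 4.25) than in the Il17rd KO library, so transcript of this gene was still counted there. Which part of Il17rc was deleted is not given in the sources used here, and a count over the whole gene does not show whether the remaining transcript is intact. In WT cells Il17rc was itself 2.42-fold lower (2.26 to 2.59) with IL-17A than without. Il17ra (chromosome 6, 120463247 to 120487559, plus strand), which encodes the shared receptor chain, had 548, 462, 577 and 558 counts and was not called in any comparison.

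**Figure D1:**
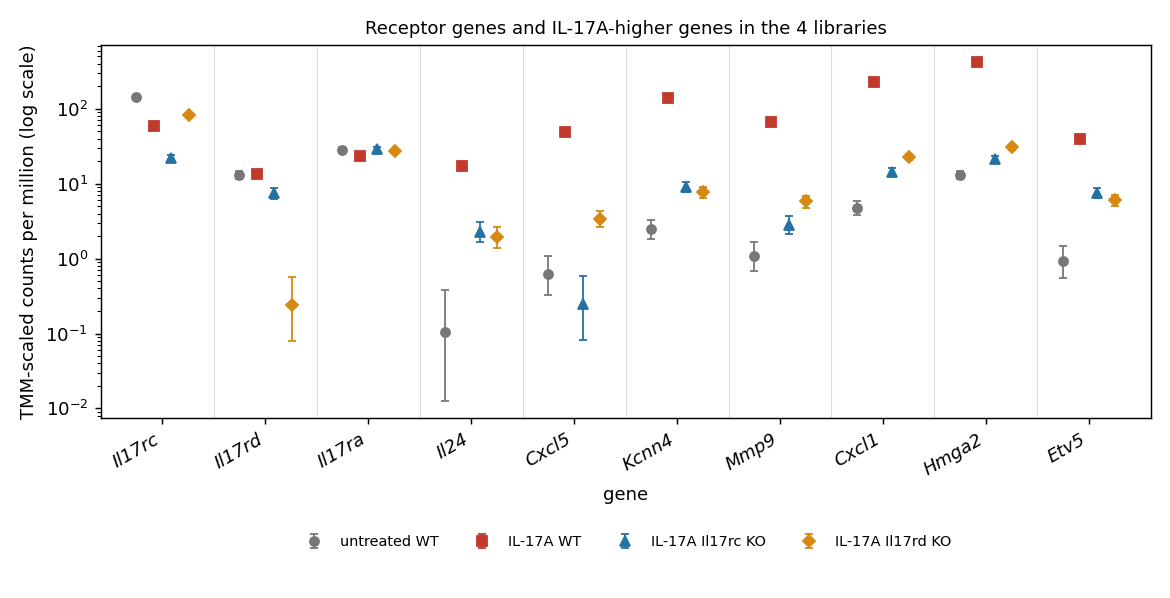
TMM-scaled CPM on a log axis for Il17rc, Il17rd, Il17ra and 7 of the genes furthest above untreated WT, with 1 point per library and bars for the exact 95% Poisson counting interval. Il17rd lies at 0.243 CPM in the Il17rd KO library, and Cxcl1 lies at 227 CPM in IL-17A WT against 14.3 and 22.8 CPM in the Il17rc KO and Il17rd KO libraries.

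WT keratinocytes with IL-17A were first compared with untreated WT cells, to describe which transcripts differed between these libraries. They also differed in sex-linked genes, as given below, so a difference cannot be assigned to the cytokine alone. Several cytokine and chemokine transcripts were among those furthest above the untreated library. Il24, a secreted cytokine, was 163-fold higher (44.8 to 1352), from 2 to 333 counts. Cxcl5 and Cxcl1, which attract neutrophils, were 77.6-fold (44.2 to 151) and 47.3-fold (38.5 to 58.8) higher, and Csf3, the granulocyte colony-stimulating factor, was 35.1-fold higher (21.8 to 60.7). In the opposite direction, Krt1 and Krt10, the keratins of differentiating epidermal cells, were 65.7-fold (61.1 to 70.7) and 53.8-fold (47.1 to 61.7) lower.

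By the rule, 1124 genes were higher and 1354 lower in IL-17A WT than in untreated WT. Besides the cytokines, the genes with the highest bounds included Kcnn4, a calcium-activated potassium channel, 56.0-fold higher (42.1 to 76.2), the gelatinase Mmp9, 61.3-fold higher (39.9 to 99.4), and the chromatin protein gene Hmga2, 31.9-fold higher (28.2 to 36.3). Il1a was 24.4-fold higher (21.5 to 27.9) and reached 6135 counts. The transcription factor genes Etv5 and Etv4 were 41.8-fold (26.3 to 70.9) and 24.3-fold (18.1 to 33.4) higher, and the receptor gene Gpr50 was 41.1-fold higher (22.8 to 83.0). mt-Atp8, a mitochondrial gene, was 44.2-fold higher (23.8 to 92.8), but it overlaps mt-Atp6, which has near-identical nuclear copies, and its count is uncertain. Near-identical copies exist for Etv5, and for Fosl1, which is named below, as well.

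Among the genes furthest below untreated WT were Wnt16, 127-fold lower (54.1 to 392.5), Sostdc1, an inhibitor of bone morphogenetic protein and Wnt signals, 64.5-fold lower (46.2 to 92.9), and the transcription factor gene Pou2f3, 76.9-fold lower (41.6 to 161). The phospholipase gene Pla2g2f was 35.9-fold lower (29.4 to 44.4) and Igfbp2 28.8-fold lower (26.2 to 31.6). Klhl38, with 100 counts in untreated WT and 0 with IL-17A, was at least 34.0-fold lower against a floor of 3 counts per library. The pseudogene Rpl28-ps1 was 63.2-fold lower (36.8 to 119). Both Klhl38 and Rpl28-ps1 have near-identical copies.

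Of the 20 measured IL-17-type cytokine and chemokine genes, 11 were higher with IL-17A, 4 lower and 5 neither, with a median log2 ratio of 1.37, at percentile 100 of 10000 random lists matched on expression. The lower members were Il33 and the interleukin-36 family genes Il1f5, Il1f8 and Il1f9, at log2 ratios of -2.11, -1.57, -1.64 and -1.31. Il1f6, of the same family, was higher, at 2.09. Of 14 antimicrobial and acute phase genes, 8 were higher and 3 lower, with a median of 1.57. Wfdc2, the S100 protein genes S100a8 and S100a9, and the protease inhibitor gene Slpi had log2 ratios of 3.86, 3.06, 2.85 and 2.89. Lcn2, an iron-sequestering protein gene chosen for mention after its values were seen, was not among them, at 54 counts with IL-17A and 85 without.

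Regulators showed a smaller spread. Of 28 genes for NF-kB feedback and IL-17 target regulators, 5 were higher and 3 lower, with a median of -0.13. Nfkbiz, Tnfaip2 and Zc3h12a, the last a ribonuclease that limits inflammatory transcripts, had log2 ratios of 1.76, 1.70 and 1.57, and Tifa was at -2.16. Among 20 genes of IL-17 receptor signalling, 0 were higher and 3 lower, namely Il17rb, Il17rc and Traf5, at -3.92, -1.27 and -1.03. The immediate early and ERK feedback list had 11 of 30 genes higher and 7 lower, with Dusp6, a phosphatase of ERK, and Fosl1 at 3.16 and 2.34. Among 14 secreted proteases and inhibitors, 7 were higher and 2 lower, with Adamts4 at 2.78 and Adamts1 at -2.23. The list of wound keratins and epidermal growth factor receptor ligands had 6 of 20 higher and 4 lower. Its urokinase receptor gene Plaur and the ligand genes Hbegf and Areg were at 3.94, 2.48 and 2.13.

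Genes of keratinocyte differentiation lay low together in IL-17A WT. Of 23 spinous and granular layer genes, 21 were lower and 0 higher than in untreated WT, with a median log2 ratio of -2.26 at percentile 0. Flg2 and Calml3 were at -5.45 and -4.12. Of 34 cornified envelope genes, 22 were lower and 3 higher, with a median of -1.73, and the late cornified envelope genes Lce1c, Lce1d, Lce1b and Lce1a2 were at -5.26, -4.54, -4.44 and -4.33. The basal keratinocyte list was mixed, with 3 of 15 higher and 2 lower, Krt15 at -3.27 and Cd44, Itga3 and Lama3 at 1.96, 1.52 and 1.11. Markers of other cells moved in the same library. Of 16 fibroblast markers, 9 were lower and 1 higher in IL-17A WT, with the collagen genes Col6a2 and Col1a2 at -4.57 and -4.01. Of 12 hair follicle markers 7 were lower and 0 higher.

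Cell cycle genes were higher with IL-17A. Of 30 measured genes 26 were higher and 0 lower, with a median log2 ratio of 1.51 at percentile 100. The replication licensing gene Cdc6, the cyclin gene Ccnd1 and Cdk1 were at 2.48, 2.43 and 1.85, and Birc5 was at 1.94. Cdc6 and Birc5 have near-identical copies. The libraries also differed in sex-linked genes. The sex and number of the mice behind each library are not given in the sources used here, so sex cannot be separated from genotype or treatment. The Y-linked Ddx3y had 654 counts in untreated WT, 233 in IL-17A WT, 749 in IL-17A Il17rc KO and 2 in IL-17A Il17rd KO. Xist, chosen after its values were seen, had 2420, 4750, 2668 and 8513 counts in that order. It matches another annotated gene by the rule for near-identical copies, and whether that gene overlaps Xist was not checked.

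**Figure D2:**
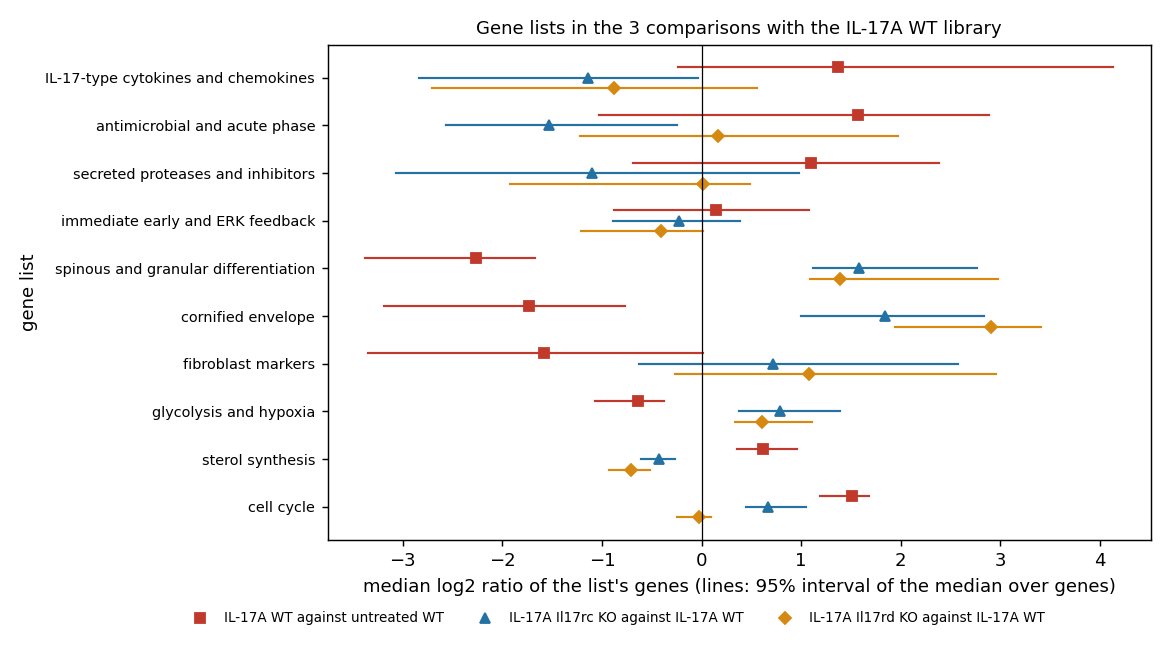
Median log2 ratio of 10 gene lists fixed in advance, on the horizontal axis, for the comparison of IL-17A WT with untreated WT and of each knockout library with IL-17A WT. Lines are the 95% interval of the median over the genes of a list, which are not replicates. Spinous and granular genes lie at -2.26 with IL-17A and at 1.58 and 1.39 in the knockout comparisons.

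The Il17rc KO library was compared with IL-17A WT to describe how the profile of cells given the same cytokine differed without Il17rc. The inflammatory transcripts that stood out in WT cells were far lower. Cxcl5 was 195-fold lower (83.2 to 602), with 5 counts against 951. Il1a was 22.9-fold (20.3 to 25.9), Csf3 20.2-fold (14.1 to 29.9) and Cxcl1 15.9-fold (14.1 to 18) lower. Differentiation genes lay in the opposite direction, with Krt1 15.99-fold higher (14.9 to 17.2).

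In total 778 genes were higher and 605 lower in the Il17rc KO library. Those with the lowest bounds also included Mmp9, 23.6-fold lower (18.1 to 31.4), Padi3, which encodes a peptidylarginine deiminase, 22.5-fold lower (17.6 to 29.4), Hmga2, 19.6-fold lower (17.8 to 21.6), and Kcnn4, 15.5-fold lower (13.3 to 18.1). The membrane protein gene Mal, the sialyltransferase gene St8sia2 and the claudin gene Cldn7 were 14.1-fold (12.6 to 15.8), 17.3-fold (12.6 to 24.3) and 16.4-fold (11.5 to 24.3) lower. On the higher side stood Prss35, 44.4-fold (23.9 to 93.2), Sostdc1, 24.6-fold (17.6 to 35.6), the homeobox gene Irx4, 22.8-fold (15.2 to 35.9), Pou2f3, 23.8-fold (12.7 to 50.3) and Megf6, 14.5-fold (12.7 to 16.7). Skint3 and Pi15 had 2 counts each in IL-17A WT and were 46.8-fold (12.6 to 392.4) and 45.4-fold (12.2 to 380) higher. The ribosomal protein pseudogenes Rpl13-ps1 and Rpl28-ps1 and the mitochondrial mt-Co2 were higher by 78.3-fold (33.3 to 242), 23.0-fold (13.3 to 43.8) and 12.9-fold (12.2 to 13.7). Rpl7a-ps11, with 0 counts, was at least 225-fold lower. These pseudogenes and mt-Co2 have near-identical copies.

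Of the 20 cytokine and chemokine genes, 10 were lower and 2 higher without Il17rc, with a median log2 ratio of -1.14 at percentile 0. The higher genes were Il33 and Tslp, at 2.48 and 1.40. Of 14 antimicrobial and acute phase genes, 9 were lower and 1 higher, with a median of -1.53. Complement C3, S100a7a, Lyz2 and Cp were at -3.73, -2.80, -2.56 and -2.56, with near-identical copies of S100a7a and Lyz2, and the defensin gene Defb1 was the higher one, at 2.41. Of 6 immune cell markers 3 were also lower and 1 higher, with Lyz2, Laptm5 and Csf1r at 67, 7 and 17 counts without Il17rc against 396, 26 and 48 in IL-17A WT and H2-Eb1 at 1.81. Zc3h12a, Tnfaip2 and Nfkbiz were the 3 lower genes among the 28 regulators, at -2.39, -2.27 and -1.42, and Tifa the 1 higher, at 1.15. Of 14 secreted proteases and inhibitors 7 were lower and 2 higher, with Adamts4 and Mmp13 at -3.07 and -2.99. The immediate early and ERK feedback list had 8 of 30 genes lower and 5 higher. Etv5, Dusp6 and Etv4 were at -2.37, -2.21 and -2.06, and Egr2 was at 2.36. Il17rb, at 2.41, was the 1 higher gene of the receptor signalling list and Il17rc, at -1.42, the 1 lower. Among wound keratins and receptor ligands 6 of 20 were higher and 4 lower, with the ligand gene Epgn at 1.93 and Plaur at -2.08.

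Of 23 spinous and granular genes, 18 were higher in the Il17rc KO library and 0 lower, with a median of 1.58 at percentile 100. Flg2, Calml3 and Krt10 were at 4.03, 3.98 and 3.29. Of 34 cornified envelope genes, 24 were higher and 2 lower, with a median of 1.84, and Lce1c, Sprr4, Lce1b and Lce3e were at 3.91, 3.54, 3.45 and 3.27, the last with a near-identical copy. Fibroblast markers moved in the same direction, 7 of 16 higher and 2 lower, with Col6a2 and Col6a3 at 3.67 and 3.16, and of 12 hair follicle markers 5 were higher and 0 lower, with a median of 0.86. Of 15 basal keratinocyte genes 3 were lower and 1 higher, with the laminin genes Lamb3 and Lama3 at -1.41 and -1.34 and Krt15 at 1.86. Cell cycle genes were higher without Il17rc than in IL-17A WT in 10 of 30 cases and lower in 0, with Cdc20, Cenpf, Mki67 and Cenpa at 1.87, 1.69, 1.57 and 1.55. Near-identical copies exist for Cenpf, Mki67 and Cenpa.

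The Il17rd KO library was compared with IL-17A WT in the same way. The cytokine genes named first for the Il17rc KO library were lower here as well, by smaller ratios. Cxcl5 was 14.3-fold lower (11.2 to 18.4), Il1a 12.9-fold (11.7 to 14.1), Csf3 12.1-fold (9.11 to 16.3) and Cxcl1 9.96-fold (9.06 to 11.0) lower. S100a8 and S100a9, which form the antimicrobial protein calprotectin, were higher by 3.76-fold (3.45 to 4.10) and 4.29-fold (3.97 to 4.65). Krt1 was 28.4-fold higher (26.4 to 30.6).

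By the rule, 781 genes were higher and 466 lower in the Il17rd KO library. Among the genes with the lowest bounds were Il17rd itself, Y-linked genes and pseudogenes. Eif2s3y, Kdm5d and Uty had 0 counts and were at least 71.4-fold, 36.4-fold and 29.0-fold lower, and Ddx3y was 122-fold lower (33.5 to 1016). Kcnn4 was 18.2-fold lower (15.5 to 21.5), Gpr50 17.96-fold (12.2 to 27.5), Mal 13.7-fold (12.3 to 15.3) and Hmga2 13.6-fold (12.5 to 14.7). mt-Atp8 was 43.0-fold lower (23.8 to 86.8), and the pseudogenes Rpl34-ps1 and Rps15a-ps5 were 100-fold (52.6 to 220) and 26.8-fold (12.02 to 74.1) lower. Higher genes included Sostdc1, 45.7-fold (32.7 to 65.8), the small proline-rich protein gene Sprr2b, 25.3-fold (20.04 to 32.3), Irx4, 27.7-fold (18.5 to 43.5), Pou2f3, 27.5-fold (14.8 to 58.0), Lce1c, 24.6-fold (14.8 to 44.5), Wnt16, 33.7-fold (14.2 to 105), and Pi15, 70.5-fold (19.2 to 588), from 2 counts. Lce3b was 41.1-fold higher (21.4 to 90.5), Klhl38 at least 20.01-fold higher, and Rpl7-ps7 and Rpl28-ps1 were 98.4-fold (38.1 to 363) and 47.9-fold (27.8 to 90.5) higher. Lce3b, Klhl38 and the pseudogenes named here have near-identical copies.

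Of 20 cytokine and chemokine genes 8 were lower and 5 higher without Il17rd, with a median log2 ratio of -0.88 at percentile 0. Il33, at 3.48, was among the higher, with Il1rn, Il1f5, Il1f8 and Il1f9 between 1.01 and 1.43. Antimicrobial and acute phase genes were 5 higher and 3 lower of 14, with Chil1 and Defb1 at 2.67 and 1.97 and a median of 0.17. Of 6 immune cell markers 2 were higher and 0 lower, with a median of 0.59. Of the 28 regulators 3 were higher and 0 lower, namely Tifa, Map3k8 and Bcl3, at 1.76, 1.15 and 1.15. Tnfaip3 was at -0.92, which is under the size called. The immediate early and ERK feedback list had 12 of 30 genes lower and 2 higher, with a median of -0.40 at percentile 0. Etv4, Dusp6, Etv5 and the ERK pathway inhibitor gene Spry4 were at -3.06, -2.83, -2.69 and -2.40. In the receptor signalling list Il17rb and Traf5 were higher, at 2.53 and 1.03. Adamts4 and Plau were at -1.93 and -1.12 among 14 proteases and inhibitors, of which 4 were lower and 1 higher.

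Spinous and granular genes were higher in 18 of 23 cases without Il17rd and lower in 0, with a median of 1.39. Krt10, Flg2 and Calml3 were at 3.96, 3.49 and 3.39. Of 34 cornified envelope genes 28 were higher and 2 lower, with a median of 2.91 at percentile 100. Wound keratins and receptor ligands were 10 higher and 4 lower of 20, with the serpin and cystatin genes Serpinb3a, Stfa1 and Serpinb3b at 3.41, 3.06 and 2.46 and Plaur at -3.01, and Stfa1 has near-identical copies. Fibroblast markers again moved in the same direction, with 9 of 16 higher and 0 lower, and of 12 hair follicle markers 5 were higher and 1 lower, with a median of 0.60. The basal keratinocyte list had 4 of 15 lower and 1 higher, with Itga3, Cd44 and Lamb3 at -1.47, -1.14 and -1.10 and Krt15 at 1.32. Among 30 cell cycle genes 1 was higher and 2 were lower, with a median of -0.03. Ccnd1 and Cdc6 were at -1.36 and -1.03, and Cenpa was at 1.08.

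The genes higher with IL-17A in WT cells were then followed into the knockout libraries. Of the 1124 genes, 343 were lower in the Il17rc KO library than in IL-17A WT and 87 were higher, and in the Il17rd KO library 334 were lower and 11 higher. The 8 genes with the highest bounds were Il24, Cxcl5, Kcnn4, Mmp9, Cxcl1, Hmga2, Etv5 and mt-Atp8. The first 7 were lower than IL-17A WT in both knockout libraries, with log2 ratios from -7.12 for Cxcl5 to -2.37 for Etv5 without Il17rc, and from -4.17 for Kcnn4 to -2.69 for Etv5 without Il17rd. mt-Atp8 was higher without Il17rc and lower without Il17rd. Against untreated WT, Il24 was still 22.0-fold (5.75 to 187) and 18.7-fold (4.84 to 159) higher in the Il17rc KO and Il17rd KO libraries. Kcnn4 was 3.62-fold (2.62 to 5.09) and 3.07-fold (2.21 to 4.34) higher, and Cxcl1 2.97-fold (2.34 to 3.80) and 4.75-fold (3.79 to 6.00) higher. Cxcl5 had 5 counts without Il17rc against 12 in untreated WT, a ratio whose interval (0.110 to 1.21) includes 1, and was 5.44-fold higher (2.93 to 11.0) than untreated WT without Il17rd.

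Over the 1124 genes the median log2 ratio against IL-17A WT was -0.45 (interval over genes -0.54 to -0.36) without Il17rc and -0.56 (-0.61 to -0.52) without Il17rd. Genes selected as high in the IL-17A WT library lie lower elsewhere by selection alone, because that library serves both steps. With its counts split at random, some to select the genes and the rest to compare, the medians were -0.40 and -0.53, which removes counting error but no other variation of that library. With 4 unchanged libraries simulated at the spread seen over all 4 libraries taken as 1 group, which holds the real differences too, 940 genes were selected and both medians were -0.54. With knockout libraries simulated as equal to IL-17A WT, both medians were -0.30 at that spread and -0.01 with counting error only. These came from 2022 and 1183 selected genes, so the -0.30 belongs to a larger set than the 1124 observed. The observed levels of the WT libraries served as true means there, so variation they already hold was added again. With the 4 unchanged libraries simulated with counting error only, 5.10 genes were selected on average. Against untreated WT, 596 of the 1124 genes were higher in the Il17rc KO library and 512 in the Il17rd KO library, with medians of 1.06 and 0.92. The genes were selected as low in that same untreated library, and in the unchanged libraries simulated at the 1-group spread these medians were both 0.80, with 357 and 355 of 940 selected genes higher. Of the 1354 genes lower with IL-17A in WT cells, 547 were higher in the Il17rc KO library than in IL-17A WT and 664 in the Il17rd KO library, and the same selection applies to them.

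**Figure D3:**
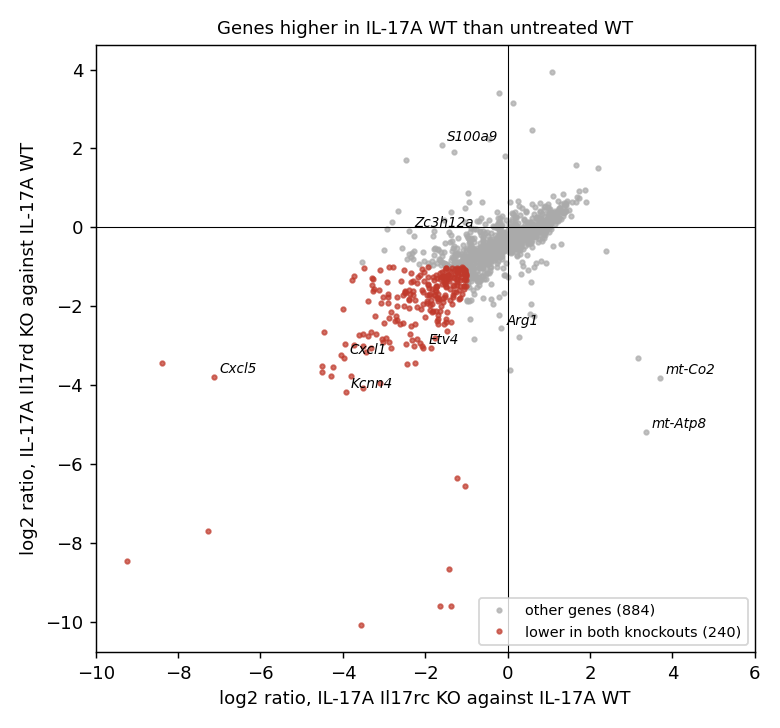
Each point is 1 of the 1124 genes higher in IL-17A WT than in untreated WT, with its log2 ratio against IL-17A WT in the Il17rc KO library (horizontal) and in the Il17rd KO library (vertical). Red points mark the 240 genes lower in both, and S100a9 lies at -1.61 and 2.10.

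In all, 240 of the 1124 genes were lower than IL-17A WT in both knockout libraries, among them Cxcl5, Il1a, Cxcl1, Csf3, Kcnn4, Hmga2 and Mmp9. Lists drawn independently within the 1124 genes would share 102. The unchanged libraries simulated at the 1-group spread shared 85.9 of 940 selected genes, with 224 and 225 lower, and knockouts simulated as equal to IL-17A WT shared 96.1 of 2022, with 305 and 304 lower, so these shared counts come from lists of other lengths. Over all tested genes 299 were lower in both and 495 higher in both, where independent lists would share 21.8 and 47.0. Independent lists are not a no-change value here, since both comparisons use the IL-17A WT library. The unchanged libraries simulated at the 1-group spread shared 228 lower and 357 higher genes, from longer lists, with 941 and 940 lower genes against the 605 and 466 observed. The log2 ratios of the knockout comparisons had a covariance of 0.398 across genes (Pearson r of 0.730), and the simulated ones 0.249 (r of 0.501) with the 1-group spread and 0.0123 (r of 0.508) with counting error only. Genes are not independent replicates, and with 1 IL-17A WT library part of the excess may come from that library.

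The knockout libraries were last compared with each other, which uses neither WT library, to describe where the profiles without Il17rc and without Il17rd differed. Several antimicrobial genes were lower without Il17rc than without Il17rd. S100a9 and S100a8 were 13.1-fold (11.6 to 15.0) and 9.35-fold (8.24 to 10.6) lower in the Il17rc KO library, and Zc3h12a was 4.95-fold lower (4.55 to 5.39). Cell cycle genes lay in the other direction, with positive log2 ratios for 30 of 30 genes.

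Here 183 genes were higher and 325 lower in the Il17rc KO than in the Il17rd KO library. The lowest bounds apart from the pseudogenes Rpl7-ps7 and Rpl7a-ps11 belonged to S100a9, S100a8, the chloride channel regulator gene Clca3a2, 14.7-fold lower (11.4 to 19.4), and Serpinb3a, 13.5-fold lower (8.59 to 22.5). Rpl7-ps7 was 67.2-fold lower (30.6 to 184) and Rpl7a-ps11 at least 20.2-fold lower. The highest were mt-Atp8, 442-fold (247 to 886), mt-Co2, 186-fold (153 to 229), Ddx3y, 384-fold (106 to 3173), and Eif2s3y, Kdm5d and Uty, at least 184-fold, 119-fold and 103-fold. Of the 28 genes that differed by 16-fold or more between the knockout libraries, 23 were mitochondrial, pseudogenes or had near-identical copies, mt-Co2 among them. Clca3a2, below that size, has a near-identical copy as well.

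Of 14 antimicrobial and acute phase genes 9 were lower without Il17rc than without Il17rd and 0 higher, with a median log2 ratio of -2.30 (-3.18 to 0.06 over genes) at percentile 0. Chil1, S100a7a and C3 were at -3.18, -2.93 and -2.50. Of 6 immune cell markers 3 were also lower and 0 higher, with a median of -0.96 at percentile 0.14. They were Lyz2, which is in both lists, Laptm5 and Csf1r, with 67, 7 and 17 counts without Il17rc and 348, 34 and 44 without Il17rd. Among the 28 regulators 3 were lower and 0 higher, and Zc3h12a, Tnfaip2 and Nfkbiz were at -2.30, -1.68 and -1.31. Without Il17rd, Zc3h12a was at 159 CPM against 170 in IL-17A WT, Nfkbiz at 205 CPM against 222 and Tnfaip2 at 30.8 CPM against 46.7. Of 20 cytokine and chemokine genes 3 were lower and 1 higher, with Cxcl5 and Il1f6 at -3.32 and -3.08 and Tslp at 1.11. Among 14 proteases and inhibitors 5 were lower and 1 higher, with Mmp13, Mmp12 and Mmp10 at -2.51, -2.09 and -1.18. Of 34 cornified envelope genes 10 were lower and 2 higher, with Sprr2i, Sprr2f and Sprr2b at -3.07, -3.01 and -2.82 and Crnn at 2.76. Spinous and granular genes differed little, with 1 of 23 lower, Tgm3 at -1.16, and a median of 0.08. In the list of wound keratins and ligands 4 of 20 were lower and 0 higher, with Stfa1 and Serpinb3b at -1.83 and -1.52. The immediate early and ERK feedback list had 3 of 30 higher and 0 lower, with Egr2 and Spry4 at 2.52 and 1.03, Etv4 2.02-fold higher and a median of 0.30 at percentile 100. Cell cycle genes had a median of 0.68, with Aurka, Plk1 and Ccna2 called higher, at 1.10, 1.08 and 1.02.

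**Figure D4:**
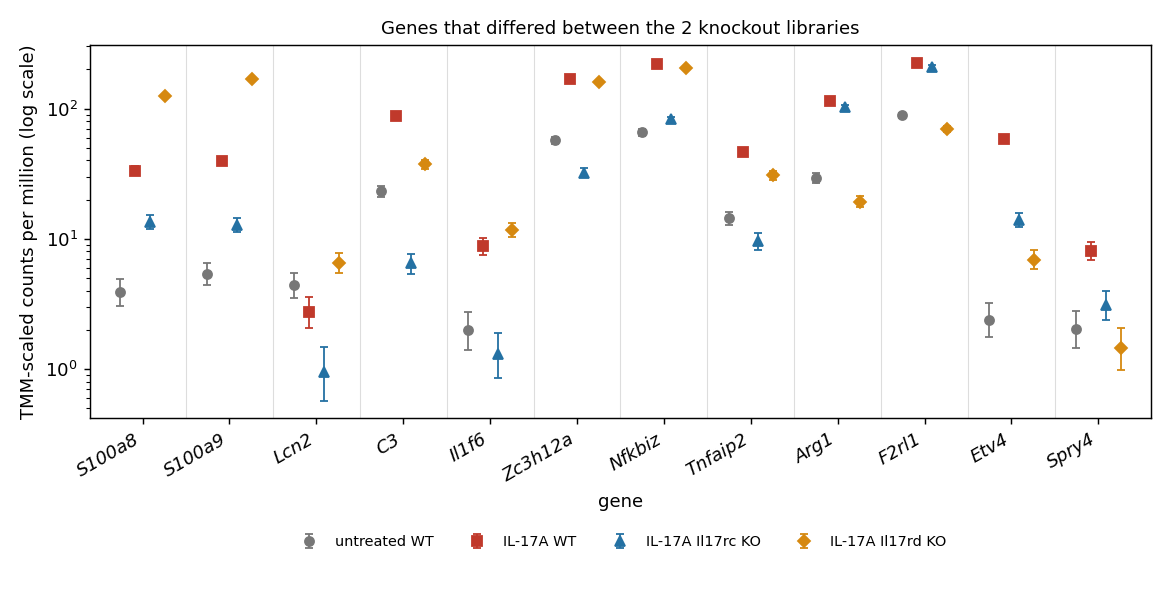
TMM-scaled CPM on a log axis for 12 genes that differed between the knockout libraries, with 1 point per library and bars for the exact 95% Poisson counting interval. S100a9 lies at 12.9 CPM without Il17rc and 169 CPM without Il17rd, and Arg1 at 102 and 19.3 CPM.

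Among the 1124 genes higher with IL-17A, 64 were lower in the Il17rc KO library both than in IL-17A WT and than in the Il17rd KO library, and 37 were lower in the Il17rd KO library both than in IL-17A WT and than in the Il17rc KO library. Without genes that have near-identical copies the counts were 50 and 20. Both conditions of a set use the same knockout library, so variation of that library alone can place genes in it. No simulated value was computed for these counts. The first set held Cxcl5, C3, Il1f6, Zc3h12a, Nfkbiz, Tnfaip2 and Mmp9, and, chosen after their values were seen, the transcription factor gene Sox11 and the membrane glycoprotein gene Pdpn, at -2.45 and -1.13 between the knockout libraries. The other set held Etv4 and Spry4 and, chosen after their values were seen, the arginase gene Arg1 and the protease-activated receptor gene F2rl1, at 2.40 and 1.58. Some members were lower than IL-17A WT in the other knockout library as well. Without Il17rd, Cxcl5 and Mmp9 were at -3.79 and -3.51, but Zc3h12a and Nfkbiz at -0.09 and -0.11. Without Il17rc, Etv4 and Spry4 were at -2.06 and -1.37, but Arg1 and F2rl1 at -0.16 and -0.10. Arg1 had 561 counts in untreated WT, 2239 in IL-17A WT, 2053 without Il17rc and 397 without Il17rd. Against untreated WT, 917 genes were higher and 871 lower in the Il17rc KO library, and 662 were higher and 412 lower in the Il17rd KO library. These comparisons differ in both genotype and treatment.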

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

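The tests on genes of 16-fold or more and on every call in families were chosen only after the result was seen, and the other test on copies was not. The genes below were past the size rule in opposite directions in the knockout libraries, both against IL-17A WT. With 1 library per group the difference was not tested.

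Lcn2, S100a8 and S100a9, which encode antimicrobial proteins, were lower without Il17rc and higher without Il17rd, and the log2 ratio of the Il17rc KO over the Il17rd KO library was -2.67, -3.21 and -3.70. Clca3a2 behaved in the same way, at -3.84, and has a near-identical copy. Crnn and Krt79, genes of the epidermis and hair follicle, were higher without Il17rc and lower without Il17rd, at 2.76 and 3.07, with 10 and 22 counts in the Il17rd KO library.

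The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y differed by 7.44, 8.07, 7.23 and 7.56 on the log2 scale. Their counts without Il17rd were 0, 0, 0 and 2, so the first 3 values depend on the prior count, and bounds are in the report. Of 5 sex-linked genes measured, 4 were lower in IL-17A WT than in untreated WT, 4 higher without Il17rc than in IL-17A WT and 4 lower without Il17rd.

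The mitochondrial genes mt-Co2, mt-Atp8 and mt-Atp6 differed by 7.51, 8.54 and 6.47. Of 11 mitochondrial genes, these were the 3 higher and 0 were lower in IL-17A WT against untreated WT, in the Il17rc KO against the IL-17A WT library and in the Il17rc KO against the Il17rd KO library. In the Il17rd KO library against IL-17A WT the same 3 were lower and 0 higher. mt-Co2 had 82, 1370, 18167 and 100 counts in untreated WT, IL-17A WT, Il17rc KO and Il17rd KO. Its nuclear copy Gm28661, chosen after its values were seen, had 2635, 113, 88 and 31191, while mt-Co1 had 84267, 101500, 109971 and 95059.

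Genes with near-identical copies made up 20.4% of the tested genes with mitochondrial genes and pseudogenes included, but 29.1%, 38.7%, 59.2% and 82.1% of the calls of 16-fold or more in the comparisons of IL-17A WT with untreated WT, of the Il17rc KO and the Il17rd KO with IL-17A WT and of the knockouts with each other. If reads were only divided differently between copies, the summed counts of a family would differ little. Over 26 such calls in families with a pseudogene or mitochondrial gene, the members had a median log2 ratio in size of 6.09 and the family sums 1.17 (interval 0.625 to 2.05), so a different division of reads is a candidate explanation for most of the size of these calls. The same limit as in the next test applies to them. Over the 192 calls whose count difference was at least 20% of the mean sum of the family, the members had 1.61 and the sums 1.12 (1.05 to 1.22), which argues against it as the whole cause of these calls, though this limit favours members that make up most of their family. Over every one of 486 calls in families the members had 1.64 and the sums 0.767 (0.651 to 0.842), which leaves open how far a different division of reads accounts for the calls in families at large, since small members hardly move a sum. Members of a family share its sum and the comparisons share libraries, so the calls are not independent and these intervals are likely too narrow. Copies counted in 1 library alone are not analysed here, no biological explanation was tested, and the mapping settings that would decide it are not given in the sources used here.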

How the results depend on the processing

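Leaving out near-identical copies and removing the GC and length trend were chosen after seeing the data; the other alternatives were planned. Of 130 values for 13 main results under 10 alternatives, 106 stayed within 1.5 times the count or within the interval of the median. Most main results are counts, which cannot reverse, and no median reversed. At 3-fold or more, a stricter rule by construction, 427 genes were higher and 655 lower with IL-17A in WT cells, 331 higher and 250 lower without Il17rc, 372 higher and 186 lower without Il17rd, and 63 higher and 110 lower between the knockouts. Against untreated WT 680 and 359 genes then differed in the Il17rc KO and Il17rd KO libraries. The IL-17A-higher genes had medians of -1.01 and -1.03, and 97 were lower in both. With a mean CPM of at least 5, which tests fewer genes, 378 were lower without Il17rc, 499 higher without Il17rd, 118 higher and 150 lower between the knockouts, and 684 differed between the Il17rd KO and untreated WT. Total counts per library moved the median without Il17rd to -0.47. The scaling of both libraries compared and the genes selected, then 1205, changed with it. Without near-identical copies, which leaves fewer genes, 116 were higher in the Il17rc KO than in the Il17rd KO library and the medians were -0.60 and -0.66. With the trend removed they were -0.58 and -0.65, and the cause was not tested. Of 580 list medians 560 stayed within their interval and 20 moved. Of the values of named genes 2757 stayed and 108 moved, with 0 reversed among those called. Leaving out the filter cannot change the value of a gene, so 573 of these had to stay. A prior count of 0.5, under which 573 stayed too, moves values toward the raw ratio inside the interval. Scaling factors differ little between settings, so they could hardly reverse a 2-fold call. Thinning says little, as totals were nearly equal. No paired analysis was possible because each group has 1 library. Depth limits genes near the floor, where 3 counts are 0.153 CPM in IL-17A WT.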

Other observations

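The tests on GC content were written before their result was seen, though the correction was added later, and those on cell types, on dishes and on the need for Il17rc were chosen only after. The medians of metabolic gene groups also differed between the libraries. Of 26 glycolysis and hypoxia genes 9 were lower and 1 higher in IL-17A WT than in untreated WT, with a median log2 ratio of -0.64. The mitophagy gene Bnip3, which has near-identical copies, the peptide hormone gene Adm and the glucose transporter gene Slc2a1 were at -3.60, -3.43 and -2.32, while Gapdh, which also has them, was at 3.46. In each knockout library 8 of these genes were higher than in IL-17A WT and 0 lower, with Bnip3 at 3.88 without Il17rc and 3.52 without Il17rd. The medians of sterol synthesis genes lay in the other direction, though most of these genes were not called. Of 22, 3 were higher and 0 lower with IL-17A in WT cells, with Idi1 and Dhcr7 at 1.39 and 1.35, and the median was 0.61, below the size called. Idi1 has near-identical copies. Without Il17rc 1 was lower and 0 higher than in IL-17A WT and without Il17rd 4 were lower and 0 higher, with medians of -0.42 and -0.71, and Dhcr7 was at -1.27 without Il17rd.

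Interferon-stimulated genes were 1 higher and 5 lower of 16 with IL-17A in WT cells, with Ifit3, Ifit1 and Ifi27 at -2.71, -2.62 and -2.01 and the chemokine gene Cxcl10 at 1.97. Ifit3 has near-identical copies. Of 16 oxidative stress genes 5 were higher and 2 lower, with Gsta4, Osgin1, Akr1b8 and Nqo1 at 3.81, 2.77, 2.33 and 1.60. Among 17 p53 targets 0 were higher and 4 lower, with Bbc3 and Sesn1 at -1.92 and -1.30. Over all tested genes 8.69% were higher and 10.5% lower in IL-17A WT than in untreated WT. In the unfolded protein and amino acid stress list 0 of 20 were higher and 1 lower, the lipoprotein receptor gene Vldlr at -1.44. Of 12 heat shock genes 1 was higher and 2 lower, with Hsp90aa1 at 1.51 and Hspa1a and Hspa1b at -2.00 and -1.72, all with near-identical copies. Of 4 replication-dependent histone genes 1 was higher and 2 lower, with Hist1h1c at -1.71.

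Some markers of other cell types differed between IL-17A WT and untreated WT. Of 10 melanocyte markers 2 were lower and 0 higher, with Pmel at -1.37. Of 6 immune cell markers 4 were lower and 0 higher, with the antigen presentation gene H2-Ab1 at -2.52 and 2.24 CPM in untreated WT. Of 5 Schwann cell markers 1 was lower and 0 higher, with a median of -0.20. Of 4 endothelial markers 1 was higher and 1 lower, with Kdr at 1.04 and Vwf at -2.56, of 3 skeletal muscle markers 1 was higher and 0 lower, with Acta1 at 1.07, and the 1 adipocyte marker measured, Fabp4, was at 0.62. Of the erythroid markers 0 were measured.

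A first pattern is that differentiation genes lay lower in the IL-17A WT library than in the other IL-17A libraries, where spinous and granular genes still had medians of -0.62 without Il17rc and -0.68 without Il17rd against untreated WT, and cornified envelope genes went both ways. Their median log2 ratio over 57 spinous, granular and cornified envelope genes was -2.02 against untreated WT, and -1.99 (interval -2.80 to -1.51) after removal of the GC and length trend, which argues against that trend as the cause. More cells of another type in the IL-17A WT library would raise their markers, but 48 fibroblast, melanocyte, immune, hair follicle and Schwann markers had a median of -0.87 (-1.37 to -0.53), which argues against more of these cells, while 8 endothelial, skeletal muscle and adipocyte markers, at 0.55 (-2.56 to 1.07), are too few to decide on theirs. That lower differentiation is a response to IL-17A that depends in part on Il17rc and Il17rd remains a hypothesis. It cannot be told apart from a WT dish that had differentiated less before or apart from IL-17A. The IL-17A WT library also differed from untreated WT in sex-linked transcripts, with 4 of 5 lower. The Il17rd KO and Il17rc KO libraries were at -0.47 (-0.73 to -0.23) and -0.37 against untreated WT. They do not decide it, since both differ from IL-17A WT in genotype, dish and sex-linked transcripts alike. WT libraries of other dishes with IL-17A would be needed.

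Another pattern is that cell cycle genes were higher in all 3 IL-17A libraries than in untreated WT. Their median of 1.51 in IL-17A WT was 1.45 (1.10 to 1.55) after removal of the GC and length trend, which argues against that trend. A response to IL-17A that needs Il17rc would leave them near untreated WT in the Il17rc KO library, where their median was 2.18 (1.77 to 2.61), with 28 of 30 higher and 0 lower, but that is 1 library, with no untreated knockout beside it. In the Il17rd KO library it was 1.51 (1.10 to 1.79), with 24 higher and 0 lower. A response that needs Il17rc hidden by an effect of the genotype or dish, a response that does not need it, and an untreated dish that grew more slowly than the others cannot be told apart, since each group has 1 library.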
